A study of Mus musculus with 55 samples.

How the data were processed

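Per the labels, bone marrow cells underwent red cell lysis and Trizol extraction, and libraries came from the TruSeq Stranded Total RNA kit with 100 bp single-end or paired-end reads. Per the submitters' processing notes, reads were handled with Bowtie2 (version 2) and RSEM (version not given in the sources used here) on mm10. The read filters, the gene annotation used by RSEM and the date of sequencing were not given in the sources used here. The deposited file of each library holds the expected count, TPM and FPKM of 46517 gene IDs from RSEM. The authors' expected counts were used for all tests and for CPM, TPM was used in the limma alternatives, and FPKM was not used. Between 8.8% and 17.7% of the expected counts per library were not whole numbers, and they were rounded before the count models. Symbols and positions came from the GENCODE vM21 annotation. It matched 46005 IDs, and the 512 unmatched ones held at most 0.213% of the counts of a library and had no symbol.

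Whether a library was single-end or paired-end is not given per sample. In the deposited files, length minus effective length was 100 in cultured libraries and 171 to 212 in uncultured ones, so no gene or list test crossed cultured and uncultured libraries. Chromosome excesses over K1_04 and the levels of a few genes were set side by side across them without a test, and may carry the difference in library type. Replicate numbers did not pair marrow libraries across groups. The library most correlated with another, after removal of group means, had the same number in 0 or 1 of 5 cases in marrow and 0 to 3 in culture. The 3 of 5 arose for H0_40 DMSO with 100 nM (median correlation of equal numbers 0.44) and for 100 nM in both origins (0.38). Other cultured pairs went down to −0.54, so a pairing in part of the cultures stays open.

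The comparisons, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except the alternative without doubted libraries. Counts were fitted in R 4.3.3 with edgeR 4.0.16 in 3 separate fits, for AML6606 marrow (10 libraries), AML6613 marrow (15) and cultured AML6606 (30). Genes passed filterByExpr by group, libraries were scaled with TMM factors, and each contrast was tested with the edgeR quasi-likelihood F-test. CPM were scaled within each fit, except levels set side by side across marrow and culture or across both leukaemias, which were scaled over all 55 libraries and so differ slightly. P-values were adjusted over all genes of a comparison by the Benjamini-Hochberg (BH) method. A gene was called changed at adjusted p under 0.05 and an absolute log2 fold change of at least 1. Differences in response were tested as contrasts of 4 groups. Named genes were 20 fixed genes, then the 8 largest rises and 8 largest falls (5 for comparisons between doses, between K1_30 and K1_26 and for the response at 100 nM) among changed genes with a mean of at least 10 CPM in the higher group and no overlap between libraries, leaving out unnamed gene models, mitochondrial genes and immune receptor segments, and up to 4 changed members per list. A few results that these rules, the Reactome sets or the tests of single libraries would include are not reported here, and all totals still count them.

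The 34 gene lists were tested with camera in limma 3.58.1 on voom log2 CPM, with a preset correlation of 0.01 between genes, for lists of at least 5 measured members. Camera compares a list with all other genes. P-values were adjusted by BH over the lists of a comparison. Of 394 tests, 130 passed, and 68 passed when the correlation was estimated from the data. Where a preset call was lost, the text gives the second value. The rotation test fry asks whether the genes of a list move on balance one way, and in its mixed form whether they move in either direction, and neither form compares a list with other genes. Counts of list members are also given with p-values adjusted over the list alone.

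The lists were the Myc network, ribosome biogenesis and growth genes bound by Myc, MAPK output genes, Ras pathway components, BET proteins and P-TEFb regulators, BET inhibitor response genes, the Wnt pathway, stem and progenitor genes, neutrophil primary and late granule genes, monocyte and macrophage genes, and antigen presentation and dendritic cell genes. Further lists held markers of B cells, T and NK cells, erythroid cells, megakaryocytes and platelets, mast cells with basophils and eosinophils, stroma, endothelium and sex. The others were G1 to S phase, G2 and M phase, cell cycle inhibitors and G1 cyclins, the BCL2 family, p53 targets, interferon response, NF-kappa B and inflammation, heat shock and stress, cholesterol synthesis, glycolysis, cytokine and growth factor receptors, drug transporters, replication-dependent histones and mitochondrially encoded genes. They were written from general knowledge and do not depend on these samples.

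Alternatives used DESeq2 1.42.0 and limma-trend on TPM. Agreement between comparisons was set against 20 simulations of unchanged groups that shared controls, and 20 splits of the controls. Chromosome medians used genes of at least 3 log2 CPM. Reactome sets of 15 to 300 genes, read with fgsea 1.28.0, were tested with camera. The gene test was tested on simulated data, in which known changes were put into the counts. Of 2-fold changes, 39.6% were recovered for H0_20 against H0_40, 30.6% for K1_26, 30.4% for K1_30, 50% for DMSO cultures and 44.9% for 250 nM in H0_40 cells and for the difference in response at 250 nM. These calls also needed an estimated fold of at least 2, which an exact 2-fold change often misses. By adjusted p alone the values were, in the same order, 54.2%, 57.1%, 56.5%, 95.8%, 85.7% and 83.7%.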

Results

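RNA sequencing was available for 55 libraries of mouse acute myeloid leukaemia (AML), in 11 groups of 5. Primary leukaemias had been transplanted into mice that received vehicle, PLX51107, an inhibitor of BET bromodomain proteins, or PLX51107 together with PD901, an inhibitor of the kinase MEK. Marrow was taken from moribund mice. In 5 groups the marrow was uncultured. These were AML6606 after vehicle (H0_40) and after PLX51107 (H0_20), and AML6613 after vehicle (K1_04) and after both drugs (K1_26 and K1_30). The other 6 groups were AML6606 cells held for 24 hours ex vivo in DMSO, 100 nM or 250 nM PLX51107. They came from vehicle marrow (H0_40) or from marrow exposed to both drugs (H0_16). The sample names carry the letter P for vehicle codes and R for drug-treated codes, and the labels explain neither the letters nor the codes. The labels also do not say that the 5 libraries of a group are separate animals or cultures, so each p-value measures only the spread among these libraries. A gene is called changed here at an adjusted p below 0.05 and a fold of at least 2. Levels are means of 5 libraries ± SD in CPM, counts scaled to library size, and log2 changes are given ± standard error. For a gene list, counts are of its measured members and the median is that of their log2 changes.

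Total counts per library ran from 30.2M to 62.6M in culture and from 21.3M to 48.9M in uncultured marrow. The biological coefficient of variation was 0.427 in AML6606 marrow, 0.482 in AML6613 marrow and 0.075 in culture, so smaller differences passed the test in culture. When 4-fold changes were simulated on the libraries of each fit, the test recovered 66.7% for H0_20 against H0_40, 72.9% for K1_26 against K1_04 and 98% for 250 nM against DMSO in H0_40 cells. The sex-linked genes separated the leukaemias. Xist, the RNA that silences one X chromosome in females, stood at 1970 to 2664 CPM in the AML6613 groups, and the Y-linked gene Ddx3y at 55.1 to 119.9 CPM in the AML6606 groups and under 1 CPM in AML6613.

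The first comparison asked how AML6606 marrow collected after PLX51107 (H0_20) differed from vehicle marrow (H0_40). Genes of the early neutrophil granule were higher in H0_20, while monocyte, inflammatory and MAPK-induced genes were lower. Xist was lower in H0_20 too, which in this Y-positive leukaemia could reflect fewer host cells. A shift in the mix of cells may therefore enter these differences, and this was not tested. Mpo (ENSMUSG00000009350, chromosome 11 from 87793581 to 87804413), which encodes myeloperoxidase, rose (989 ± 164 against 318 ± 20.8 CPM, log2 change 1.64 ± 0.10, adjusted p = 1.83e-10). Elane, neutrophil elastase, rose by 2.23 ± 0.11, and Fcnb, a granule ficolin, by 3.48 ± 0.34. Among primary granule genes 6 of 13 rose and 0 fell (median 0.90, camera adjusted p = 2.2e-08). Late granule genes also shifted upward, and 5 of 20 rose and 1 fell (median 0.27, camera adjusted p = 0.00648). Cd177, a neutrophil surface protein, rose from 115 to 404 CPM (1.82 ± 0.07, adjusted p = 1.05e-12). Of the monocyte and macrophage genes, 2 of 21 rose and 8 fell, or 2 rises and 9 falls adjusted over the list alone (median −1.13, camera adjusted p = 0.000184). They included Mrc1, the mannose receptor (33.4 ± 5.66 against 188 ± 10.5 CPM, adjusted p = 1.69e-12), Itgax, an integrin of myeloid cells (−2.04 ± 0.13), and Cd14, a co-receptor for bacterial lipopolysaccharide (−1.69 ± 0.11), whereas F13a1, a coagulation factor of monocytes, rose (2.01 ± 0.07). Among NF-kappa B and inflammatory genes, 7 of 20 fell and 0 rose, or 0 rises and 8 falls adjusted over the list alone (median −0.61, camera adjusted p = 8.89e-06). The chemokine genes Ccl2 (−3.74 ± 0.24), Ccl3 (−1.91 ± 0.07) and Ccl4 (−2.12 ± 0.08) were among them.

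MAPK output genes, which report signalling below Ras, were lower in H0_20, and 7 of 23 fell and 0 rose (median −0.71, camera adjusted p = 2.23e-06). Egr1, an immediate early transcription factor, fell from 103 to 36.4 CPM (−1.50 ± 0.10, adjusted p = 6.93e-10), and Fos by −2.05 ± 0.41. Dusp6 (ENSMUSG00000019960, chromosome 10 from 99263231 to 99267489), a phosphatase that restrains ERK, had a log2 difference of −0.97 ± 0.07, adjusted p = 4.78e-09, just short of the fold minimum. It reached −1.01 without library 4 of H0_40. Among Ras pathway components 1 of 38 rose and 2 fell (median −0.14, camera adjusted p = 0.444), with Dab2ip, a RasGAP, at −2.18 ± 0.17. Myc (ENSMUSG00000022346, chromosome 15 from 61985391 to 61990374) differed by 0.45 ± 0.08, adjusted p = 0.000297, below the fold minimum. Its network genes had a median of 0.33 (0 of 10 changed, camera adjusted p = 0.0161, adjusted p = 0.06 with an estimated correlation). Ribosome biogenesis and growth genes bound by Myc did not move as a list (1 of 50 rose and 1 fell, median 0.02, camera adjusted p = 0.701). Glycolysis genes were higher (4 of 16 rose and 0 fell, median 0.68, camera adjusted p = 9e-17, adjusted p = 0.0543 with an estimated correlation), among them Pfkl (1.45 ± 0.12), Pfkp (1.44 ± 0.07) and Tpi1 (1.05 ± 0.07). G2 and M phase genes shifted upward with no member past the fold minimum (0 of 29 changed, median 0.47, camera adjusted p = 4.16e-12). So did G1 to S phase genes (0 of 32 changed, median 0.19, camera adjusted p = 0.00395). Cell cycle inhibitors and G1 cyclins did not pass as a list (3 of 15 fell and 0 rose, median 0.01, camera adjusted p = 0.923), although Ccnd2, cyclin D2, fell by −1.61 ± 0.08.

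In all, 851 of 13729 genes changed between H0_20 and H0_40, 337 higher and 514 lower. The excess of falls depended on the scaling, since library totals without composition factors gave 518 higher and 419 lower. The largest rises under the naming rule were Ak4, Tgm2, Ptprr, Hif3a, Fcnb, Plcxd2, Il1r2 and Gemin4, from 5.42 ± 0.35 for Ak4, an adenylate kinase, to 3.06 ± 0.85 for Gemin4. The largest falls were Cyp3a41a (0.273 against 83.7 CPM, −8.24 ± 0.19), Slc47a1, Tex19.1, Morc1, Ccl12, Slc6a4, Xlr and Clec10a (−4.43 ± 0.29). Tex19.1 and Morc1 are germline genes. Markers of other cells moved too. Pf4 and Ppbp, platelet chemokine genes, were lower (−2.51 ± 0.29 and −2.54 ± 0.41). So were Gata2 (−2.83 ± 0.30) and Hdc (−3.18 ± 0.39) of the mast cell, basophil and eosinophil list (2 of 5 fell and 0 rose, median −1.85, camera adjusted p = 0.125). Xist stood at 17.4 CPM in H0_20 and 79.4 CPM in H0_40 (−2.20 ± 0.25, adjusted p = 1.72e-06), among sex-linked genes of which 1 of 5 fell and 0 rose (median −0.11, camera adjusted p = 0.354). Cytokine and growth factor receptors had 3 falls among 16 measured members (median −0.41, camera adjusted p = 0.0799). Mitochondrially encoded genes had a median of −0.27 (1 of 13 rose and 1 fell, camera adjusted p = 0.0161, adjusted p = 0.425 with an estimated correlation). Genes on chromosome 12 were lower as a body in H0_20, with a median of −0.52 against 0.01 for the other autosomes, and 37 of the 514 falls lay there. Library 3 of H0_40 stood apart on the second principal component (89.9 against −32.6 to −22.6 in the other 4), and 858 genes changed without it and library 4 of H0_20. Counts adjusted over the list alone equalled those given except where shown.

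**Figure D1:**
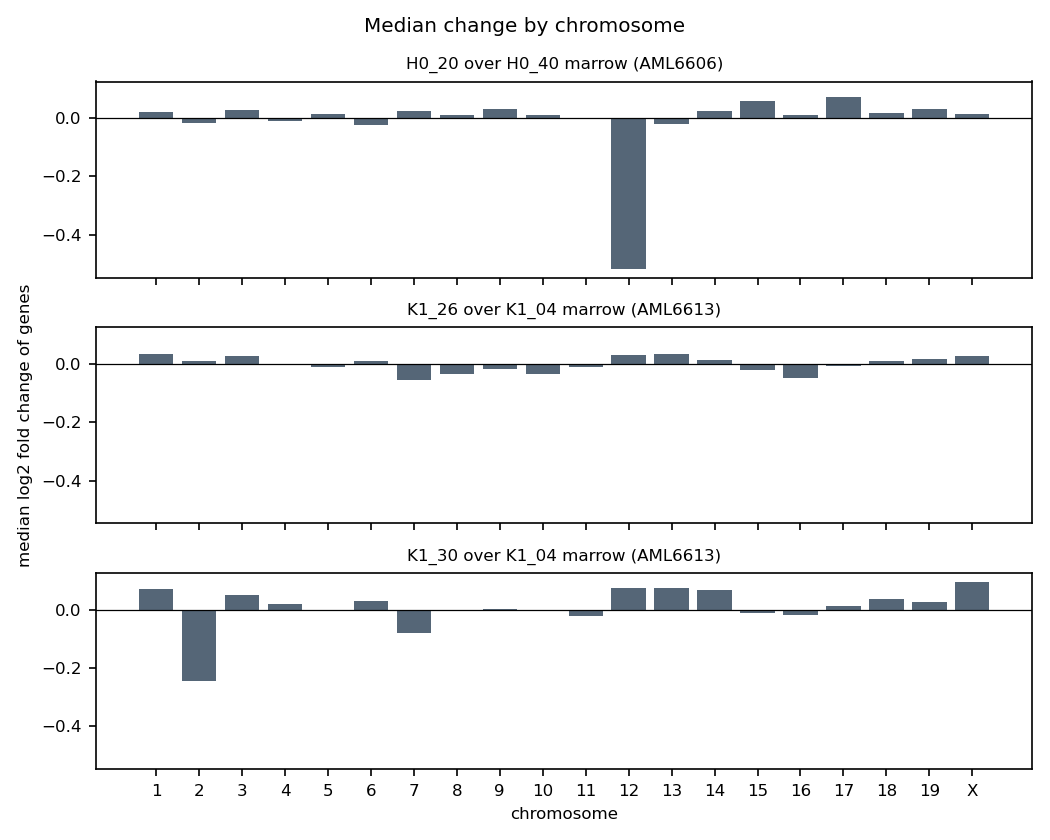
Median log2 change of the genes on each chromosome in 3 comparisons of uncultured marrow. Bars show H0_20 against H0_40, K1_26 against K1_04 and K1_30 against K1_04; the lowest were chromosome 12 in H0_20 (−0.52) and chromosome 2 in K1_30 (−0.24).

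For AML6613 the question was how marrow collected after both drugs differed from vehicle marrow (K1_04), in each of the codes K1_26 and K1_30. In K1_26 marrow, neutrophil granule genes were lower and antigen presentation genes higher than in K1_04. Mpo fell to 322 ± 9.13 CPM from 938 ± 105 (−1.54 ± 0.10, adjusted p = 1.3e-10), Elane by −1.79 ± 0.12 and Ctsg, cathepsin G, by −1.85 ± 0.11. Primary granule genes fell as a list (5 of 13 fell and 0 rose, median −0.79, camera adjusted p = 6.72e-19). Late granule genes fell further (1 of 16 rose and 9 fell, median −1.31, camera adjusted p = 4.38e-15), with Ngp at −3.40 ± 0.43 and Cd177 at −2.30 ± 0.31. MAPK output genes were lower (5 of 22 fell and 0 rose, median −0.56, camera adjusted p = 0.000773), among them Spry2, a feedback inhibitor of receptor signalling (4.15 against 12.3 CPM, −1.57 ± 0.31), Etv4 (−1.70 ± 0.30) and Fosl1 (−1.34 ± 0.20). Dusp6 had −0.70 ± 0.13, adjusted p = 0.000514, within the fold minimum. Of the Ras pathway components, 1 of 40 rose and 1 fell (median 0.00, camera adjusted p = 0.701). Rasgrp1, an exchange factor that loads Ras with GTP, rose from 2.12 ± 1.26 to 15.3 ± 4.59 CPM (2.85 ± 0.36, adjusted p = 5.63e-06). Myc differed by −0.22 ± 0.07, adjusted p = 0.0373, and the stem cell marker Cd34 fell (31.0 against 77.2 CPM, −1.32 ± 0.12).

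Antigen presentation and dendritic cell genes rose as a list in K1_26 without a member past the fold minimum (0 of 14 changed, median 0.54, camera adjusted p = 4.61e-07). NF-kappa B and inflammatory genes were lower (1 of 22 rose and 2 fell, or 1 rises and 4 falls adjusted over the list alone, median −0.40, camera adjusted p = 0.000646), with Plaur, the urokinase receptor, at −1.54 ± 0.11. Cholesterol synthesis genes shifted downward (0 of 21 changed, median −0.31, camera adjusted p = 4.07e-09). Genes of G2 and M phase were slightly higher (0 of 29 changed, median 0.20, camera adjusted p = 2.89e-10). Erythroid genes had a median of 1.96 (1 of 9 rose and 0 fell, or 2 rises and 0 falls adjusted over the list alone, camera adjusted p = 0.00099). Hbb-bt, a haemoglobin chain, rose from 4.56 ± 1.77 to 18.3 ± 5.65 CPM. Glycolysis genes (median −0.18, camera adjusted p = 2.26e-05, adjusted p = 0.251 with an estimated correlation) and interferon response genes (median 0.36, camera adjusted p = 0.0156, adjusted p = 0.154 with an estimated correlation) passed only with the preset correlation, with 0 members of either list changed. The BET inhibitor response list passed narrowly (1 of 17 fell and 0 rose, median −0.17, camera adjusted p = 0.0429, adjusted p = 0.154 with an estimated correlation; adjusted p = 0.0776 with replicate number as a block). In all, 356 of 14187 genes changed, 139 higher and 217 lower. Library 5 of K1_26 stood apart on the second principal component (110.4 against 17 to 44.3 in the other 4), and 362 genes changed without it and library 5 of K1_30. The largest rises were Gzmb, granzyme B (45.8 against 4.91 CPM, 3.23 ± 0.20), Chd3, Rasgrp1, Arhgap5, Tbc1d4, Tjp1, Scd3 and Arhgap12. The largest falls were Tfpi, an inhibitor of coagulation (0.675 against 10.7 CPM, −3.97 ± 0.52), Stfa1, Itgb3, Ngp, Cst7, Gja1, Pcdh7 and Penk. Counts adjusted over the list alone equalled those given except where shown.

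In K1_30 marrow the same question gave larger differences from K1_04. Late granule genes fell by a median log2 of −2.48 (12 of 16 fell and 0 rose, camera adjusted p = 5.53e-15), with Lcn2, lipocalin 2, at 1.27 against 17.3 CPM, −3.76 ± 0.26 and Mmp8, neutrophil collagenase, at −3.69 ± 0.26. Primary granule genes fell as well (6 of 13 fell and 0 rose, median −0.96, camera adjusted p = 2.4e-08), with Mpo at −1.71 ± 0.10 and Prtn3, proteinase 3, at −1.75 ± 0.11. Monocyte and macrophage genes were lower (7 of 22 fell and 0 rose, or 1 rises and 8 falls adjusted over the list alone, median −0.55, camera adjusted p = 2.34e-05), among them Lyz2, lysozyme (90.7 against 524 CPM, −2.53 ± 0.08), Csf1r, the receptor for macrophage growth factor (−1.24 ± 0.10), and Cd14 (−4.45 ± 0.39). Antigen presentation and dendritic cell genes rose (7 of 14 rose and 0 fell, median 0.97, camera adjusted p = 1.1e-10), with H2-Aa, an MHC class II chain, at 154 against 60.0 CPM, 1.35 ± 0.10 and Cd209a at 2.18 ± 0.42. MAPK output genes had a median of −1.10 (9 of 22 fell and 0 rose, or 0 rises and 11 falls adjusted over the list alone, camera adjusted p = 5.14e-09), with Egr1 at −2.76 ± 0.28 and Fosl1 at −1.86 ± 0.21. Dusp6 fell by −1.07 ± 0.13, or −0.99 without library 4 of K1_30, and Spry2 by −1.12 ± 0.30, or −0.97 without library 2 of K1_30, both then short of the fold minimum. Among Ras pathway components 2 of 40 rose and 1 fell (median −0.18, camera adjusted p = 0.114), with Rras2 at 1.44 ± 0.17 and Rasgrp1 at 2.03 ± 0.35. Myc differed by −0.06 ± 0.07, adjusted p = 0.643. Of the BCL2 family, 1 of 15 rose and 1 fell (median −0.10, camera adjusted p = 0.28). Bcl2, which blocks apoptosis, rose (108 against 52.8 CPM, 1.03 ± 0.10) and Bcl2l1 fell (−1.84 ± 0.15).

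G1 to S phase genes were higher in K1_30 (0 of 32 changed, median 0.21, camera adjusted p = 4.2e-08). Those of G2 and M phase were lower (0 of 29 changed, median −0.23, camera adjusted p = 1.19e-05). Cholesterol synthesis genes were lower (0 of 21 changed, median −0.43, camera adjusted p = 3.54e-10). NF-kappa B and inflammatory genes were lower too (2 of 22 rose and 6 fell, or 2 rises and 8 falls adjusted over the list alone, median −0.70, camera adjusted p = 4.49e-05), with Ccl2 at −5.04 ± 0.69 and Plaur at −2.73 ± 0.12. Heat shock and stress genes passed narrowly (3 of 16 fell and 0 rose, or 0 rises and 4 falls adjusted over the list alone, median −0.21, camera adjusted p = 0.0482, adjusted p = 0.186 with an estimated correlation). So did B cell genes (1 of 6 rose and 0 fell, median 1.88, camera adjusted p = 0.0449, adjusted p = 0.132 with an estimated correlation). With replicate number as a block, both lost their calls, at adjusted p = 0.0675 and 0.0765. Cytokine and growth factor receptors were lower only with the preset correlation (1 of 17 rose and 3 fell, median −0.16, camera adjusted p = 0.00777, adjusted p = 0.0805 with an estimated correlation). The same held for the mast cell, basophil and eosinophil list (1 of 9 rose and 3 fell, or 1 rises and 4 falls adjusted over the list alone, median −0.77, camera adjusted p = 0.0181, adjusted p = 0.0527 with an estimated correlation) and for glycolysis genes (median −0.36, camera adjusted p = 8.59e-07, adjusted p = 0.132 with an estimated correlation). Mitochondrially encoded genes had a median of 0.38 (camera adjusted p = 1.46e-05, adjusted p = 0.132 with an estimated correlation), and their share of all counts was 4.35 ± 0.46% in K1_30 and 3.51 ± 0.08% in K1_04. In all, 697 of 14187 genes changed, 290 higher and 407 lower. The largest rises were Tnfrsf9, a receptor of the tumour necrosis factor family (25.6 against 1.83 CPM, 3.81 ± 0.36), Tceal8, Tbc1d4, Gzmb, Stk39, Cecr2, Dglucy and Ccl22. The largest falls were Rnf217 (0.188 against 10.4 CPM, −5.63 ± 0.45), Stfa1, Stfa2l1, Ccl2, Cd14, Gpr84, Selp and Serpinb2. Genes on chromosome 2 had a median of −0.24 against 0.01 for the other autosomes, and 49 of the 407 falls lay there. Counts adjusted over the list alone equalled those given except where shown.

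K1_30 was then set against K1_26, since both came from marrow exposed to both drugs. Monocyte and macrophage genes were lower in K1_30 (2 of 22 rose and 5 fell, or 3 rises and 8 falls adjusted over the list alone, median −0.60, camera adjusted p = 0.000459), with Mrc1 at 1.87 against 18.9 CPM, −3.36 ± 0.38 and Lyz2 at −1.96 ± 0.07. Late granule genes were lower too (8 of 16 fell and 0 rose, median −1.35, camera adjusted p = 2.11e-05). G2 and M phase genes were lower (1 of 29 fell and 0 rose, median −0.39, camera adjusted p = 5.87e-26). G1 to S phase genes were higher (0 of 32 changed, median 0.20, camera adjusted p = 1.43e-06).  MAPK output genes were lower again (3 of 22 fell and 0 rose, median −0.52, camera adjusted p = 0.000459), with Egr1 at −1.57 ± 0.27. The p53 target genes were slightly higher (1 of 20 rose and 0 fell, median 0.16, camera adjusted p = 0.00679). Perp rose by 2.15 ± 0.18. Antigen presentation and dendritic cell genes were higher (2 of 14 rose and 0 fell, or 3 rises and 0 falls adjusted over the list alone, median 0.42, camera adjusted p = 0.00048). Reactome sets with related names gave 2 directions. The set named MHC class II antigen presentation was lower (75 genes, 1 fell and 0 rose, median −0.16, camera adjusted p = 0.00111, and 0.0273 with an estimated correlation). It is much larger than the fixed list of 14 measured genes, so it does not show a fall of the MHC class II chains themselves. Class I folding and peptide loading was higher (29 genes, median 0.17, camera adjusted p = 0.0113, and 0.0462 with an estimated correlation). NF-kappa B and inflammatory genes were lower (1 of 22 rose and 5 fell, median −0.26, camera adjusted p = 0.0179). In all, 395 of 14187 genes changed, 181 higher and 214 lower, and 339 without library 5 of either code. The balance of rises and falls turned in some alternatives, given below. The largest rises were Tceal8, Rec114, Evl, Tnfrsf9 and Cpa3, a mast cell carboxypeptidase (30.8 against 4.63 CPM, 2.73 ± 0.22), and the largest falls Rnf217, Gpnmb (4.01 against 68.0 CPM, −4.06 ± 0.18), Selp, Mrc1 and Msr1, a scavenger receptor of macrophages. Unlike Cpa3, the mast cell, basophil and eosinophil list had a median below 0 (−0.68). Bcl2 rose by 1.01 ± 0.10, or 0.92 without library 4 of K1_26, then short of the fold minimum. The median of chromosome 2 genes was −0.27 here, and 30 of the 214 falls lay there.

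The changes of K1_26 and K1_30 from K1_04 could be compared gene by gene, although both used the same 5 control libraries. Of the genes changed in both, 90 were higher in both and 105 lower in both, where independent draws would give 2.8 and 6.2, and 2 went opposite ways. Mpo, Elane, Stfa1, Cd14 and Plaur fell in both, and Gzmb, Tbc1d4 and Rasgrp1 rose in both. The log2 changes had a correlation of 0.521. Unchanged groups sharing controls gave 0.494 in simulation, so the correlation alone carries little, but the covariance was 0.449 against 0.242 in simulation. With the control libraries split between the comparisons the correlation was 0.259. On average 268.7 genes then changed in K1_26 and 536.5 in K1_30, of which 42 were higher in both, 82.2 lower in both and 1.4 opposite. Simulated unchanged groups gave 0 shared genes, but they had only 0 and 0.2 genes changed at all, so that 0 offers no contrast. The AML6606 change from H0_40 to H0_20 had correlations of 0.097 with K1_26 and 0.171 with K1_30. With K1_30 it shared 95 falls (12.9 by independent draws) and 8 rises (4.6), and 28 genes went opposite ways (15.6). Genes are not independent replicates, so these correlations carry no p-value. Granule genes were among those that went opposite ways, with Mpo at 1.64 in H0_20 and −1.71 in K1_30.

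**Figure D2:**
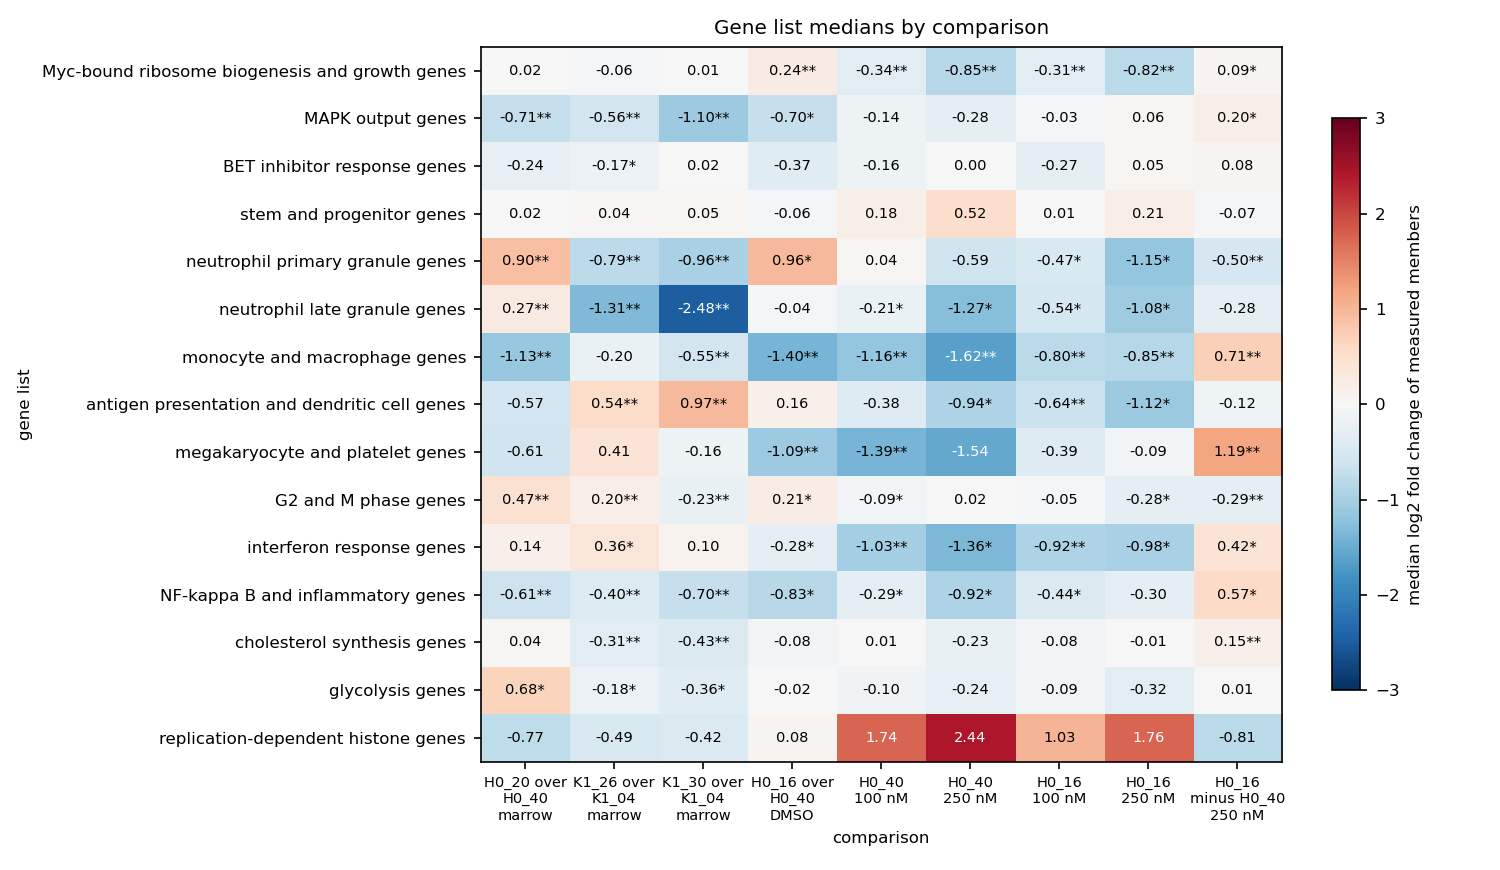
Median log2 change of 15 gene lists in 9 comparisons. Colour gives the median, 1 star a camera adjusted p below 0.05 and 2 stars that it also passed with an estimated correlation.

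In culture, the question of what differed before any ex vivo drug was put by comparing DMSO-treated AML6606 cells from H0_16 with those from H0_40. Mpo, some other granule genes and Kit were higher in H0_16 cells, and monocyte and platelet genes were lower as lists. Mpo stood at 5486 ± 268 CPM in H0_16 and 856 ± 82.0 CPM in H0_40 (2.68 ± 0.07, adjusted p = 2.9e-23). Kit, the stem cell factor receptor, stood at 20.7 ± 1.22 and 1.75 ± 0.151 CPM (3.56 ± 0.08, adjusted p = 2.7e-24). Gfi1, a repressor needed for neutrophil formation, rose by 4.51 ± 0.20 and Elane by 1.85 ± 0.11 among primary granule genes (7 of 14 rose and 1 fell, median 0.96, camera adjusted p = 7.8e-05, adjusted p = 0.121 with an estimated correlation). Late granule genes were mixed (8 of 20 rose and 3 fell, median −0.04, camera adjusted p = 0.657), with Camp at 3.70 ± 0.11 and Ngp at 2.67 ± 0.04. Monocyte and macrophage genes were lower (15 of 21 fell and 0 rose, median −1.40, camera adjusted p = 4.96e-15), including Fn1, fibronectin (68.3 against 639.5 CPM, −3.23 ± 0.07), and Mrc1 (−2.78 ± 0.07). Megakaryocyte and platelet genes were lower (4 of 8 fell and 0 rose, median −1.09, camera adjusted p = 0.00123), with Ppbp at −4.17 ± 0.12 and Pf4 at −3.43 ± 0.17. NF-kappa B and inflammatory genes were lower with the preset correlation (8 of 21 fell and 0 rose, median −0.83, camera adjusted p = 1.48e-08, adjusted p = 0.0733 with an estimated correlation), and interferon response genes too (1 of 25 rose and 5 fell, median −0.28, camera adjusted p = 0.00747, adjusted p = 0.121 with an estimated correlation). Stem and progenitor genes did not pass as a list (3 of 15 rose and 0 fell, median −0.06, camera adjusted p = 0.848).

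MAPK output genes were lower in H0_16 cells with the preset correlation (3 of 22 fell and 0 rose, median −0.70, camera adjusted p = 0.000129, adjusted p = 0.193 with an estimated correlation), with Egr1 at −1.46 ± 0.09. Dusp6 (−0.78 ± 0.04), Spry2 (−0.78 ± 0.05) and Etv5 (−0.55 ± 0.03) had lower values within the fold minimum, while Ccnd1, cyclin D1, had 0.51 ± 0.04. Ras pathway components did not pass as a list (4 of 39 fell and 0 rose, median −0.07, camera adjusted p = 0.136), although Gab1, an adaptor that feeds Ras, fell (0.651 against 4.50 CPM, −2.79 ± 0.11). Myc was at 319 and 307 CPM (0.06 ± 0.08, adjusted p = 0.588). Ribosome biogenesis and growth genes were slightly higher (0 of 50 changed, median 0.24, camera adjusted p = 1.1e-09). G2 and M phase genes were higher with the preset correlation (0 of 29 changed, median 0.21, camera adjusted p = 1.85e-06, adjusted p = 0.077 with an estimated correlation). In all, 1147 of 14966 genes changed, 279 higher and 868 lower. The largest rises were Lipg, Ankrd37, Camp, Xlr, Kit, Myl10, Car12 and Tgm2. The largest falls were Arhgap21 (0.543 against 74.7 CPM, −7.11 ± 0.08), Pkp4, Ly75, Mmp13, Clcf1, Ppbp, Retnla and Vsig8, of which the first 3 lie on chromosome 2. That chromosome was not lower as a body (median 0.03 against 0.05 for the other autosomes), and 68 of the 868 falls lay there. Together with the H0_20 change in uncultured marrow, 32 genes were higher in both and 213 lower in both (4.3 and 27.2 by independent draws), 37 went opposite ways (25), and the correlation was 0.245. These comparisons share no library, but both set a drug-exposed code against H0_40.

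The ex vivo response to PLX51107 was measured first in cells from vehicle marrow (H0_40), at 100 nM and 250 nM against DMSO. Myc fell from 307 ± 35.7 CPM in DMSO to 171 ± 19.5 at 100 nM (−0.84 ± 0.08, within the fold minimum) and 90.3 ± 9.37 at 250 nM (−1.76 ± 0.09, adjusted p = 2.46e-17). Hexim1 (ENSMUSG00000048878, chromosome 11 from 103116231 to 103119725), an inhibitor of P-TEFb whose RNA rises under BET inhibition, went from 45.0 ± 4.90 to 84.1 ± 10.4 and 116 ± 11.3 CPM (0.90 ± 0.08, within the fold minimum, and 1.37 ± 0.08, adjusted p = 6.82e-15). Ccnd1 (ENSMUSG00000070348, chromosome 7 from 144929931 to 144939925) fell from 119.6 ± 5.06 to 17.5 ± 0.868 and 3.92 ± 0.293 CPM (−2.77 ± 0.05 and −4.94 ± 0.06). Of the BET inhibitor response genes, 6 rose and 3 fell of 18 at 100 nM and 7 and 5 at 250 nM. The list holds genes known to move either way, so its balance did not pass (median 0.00, camera adjusted p = 0.838 at 250 nM), while the rotation test for movement in either direction gave adjusted p = 1.86e-23. That form passed in 346 of the 394 list tests, so it does not set this list apart from other genes. Cd180, a receptor of the Toll-like family, fell (−4.52 ± 0.16) and Serpini1 rose (2.81 ± 0.18). BET proteins and P-TEFb regulators were slightly higher at 250 nM (1 of 18 rose and 1 fell, median 0.28, camera adjusted p = 0.00107), with Brd2 at 0.80 ± 0.03 within the fold minimum. Ribosome biogenesis and growth genes fell at 250 nM (17 of 50 fell and 0 rose, median −0.85, camera adjusted p = 2.62e-19), among them Srm, spermidine synthase (−1.58 ± 0.06), and Ldha (−1.34 ± 0.02). At 100 nM their median was −0.34 with 0 members changed (camera adjusted p = 6.53e-15). The Myc network did not pass as a list (2 of 10 rose and 1 fell, median 0.06, camera adjusted p = 0.576), and Mxd4, an antagonist of Myc, rose (1.38 ± 0.05).

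Monocyte and macrophage genes fell in H0_40 cells at 250 nM (14 of 21 fell and 0 rose, median −1.62, camera adjusted p = 1.36e-06), with Mrc1 at 3.32 against 152 CPM, −5.50 ± 0.09. They fell already at 100 nM (11 of 21 fell and 0 rose, median −1.16, camera adjusted p = 3.68e-09). Interferon response genes fell at 100 nM (13 of 25 fell and 0 rose, median −1.03, camera adjusted p = 3.15e-07). At 250 nM 16 of 25 fell and 0 rose (median −1.36, camera adjusted p = 0.000802, adjusted p = 0.081 with an estimated correlation), with Oasl1 at −4.26 ± 0.10 and Oas2 at −3.91 ± 0.18. NF-kappa B and inflammatory genes were lower at 250 nM (1 of 21 rose and 10 fell, median −0.92, camera adjusted p = 0.000802, adjusted p = 0.246 with an estimated correlation), with Ccl2 at −5.27 ± 0.12. Antigen presentation genes were lower likewise (5 of 12 fell and 0 rose, median −0.94, camera adjusted p = 0.0123, adjusted p = 0.081 with an estimated correlation). Late granule genes split, and 3 of 20 rose and 11 fell (median −1.27, camera adjusted p = 0.00623, adjusted p = 0.333 with an estimated correlation). S100a9, a calcium-binding alarmin, rose (2076 against 283 CPM, 2.88 ± 0.06) with Cd177 (2.76 ± 0.04), while Retnlg (−6.09 ± 0.09), Mmp8 (−4.93 ± 0.10) and Chil3 (−4.40 ± 0.06) fell. Primary granule genes did not pass (2 of 14 rose and 4 fell, median −0.59, camera adjusted p = 0.589), and Mpo had 0.71 ± 0.07, within the fold minimum. Megakaryocyte and platelet genes fell at 100 nM (5 of 8 fell and 0 rose, median −1.39, camera adjusted p = 0.0274), with Ppbp at −4.40 ± 0.12. At 250 nM they had 4 falls of 8 (median −1.54, camera adjusted p = 0.0563). Replication-dependent histone genes, few of them measurable, had 9 rises of 11 at 250 nM (10 adjusted over the list alone; median 2.44, camera adjusted p = 0.0728). The linker histone gene Hist1h1c was among the rises at 100 nM (1.66 ± 0.08). G1 to S phase genes were lower with the preset correlation (0 of 32 changed, median −0.27, camera adjusted p = 0.000557, adjusted p = 0.081 with an estimated correlation), while G2 and M phase genes were not (0 of 29 changed, median 0.02, camera adjusted p = 0.923). Of the BCL2 family, 2 of 15 rose and 2 fell (median −0.16, camera adjusted p = 0.589), with rises of the apoptosis promoters Bmf (2.48 ± 0.08) and Bcl2l11 (1.59 ± 0.04).

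The remaining lists of cell identity and signalling in H0_40 cells at 250 nM are given for completeness. Among T and NK cell genes 3 of 4 fell and 0 rose (median −1.50, too few members for camera), led by the co-stimulatory receptor gene Cd28 (−4.72 ± 0.14). For B cell genes 3 of 6 fell and 0 rose (median −0.98, camera adjusted p = 0.328). For erythroid genes 1 of 4 fell and 0 rose (median −0.68, too few members for camera), and the fall was in Tfrc, the transferrin receptor. Endothelial genes had 2 falls of 4 (median −1.05, too few members for camera) and stromal genes 2 of 4 (median −0.50, too few members for camera). These were led by Pecam1 (−4.24 ± 0.07) and Spp1 (−2.20 ± 0.07), which myeloid cells also express. Stem and progenitor genes did not pass (1 of 15 rose and 2 fell, median 0.52, camera adjusted p = 0.401), and Gata2 fell (−5.03 ± 0.15). Neither did p53 target genes (2 of 20 rose and 5 fell, median −0.36, camera adjusted p = 0.136), which at 100 nM had adjusted p = 0.0486 with the preset correlation, 0.072 with an estimated correlation and 0.0518 with replicate number as a block. Nor did MAPK output genes (1 of 22 rose and 5 fell, median −0.28, camera adjusted p = 0.392) or Ras pathway components (1 of 39 fell and 0 rose, median 0.16, camera adjusted p = 0.136). Drug transporters (1 of 7 fell and 0 rose, median −0.26, camera adjusted p = 0.0759) and Wnt pathway genes (2 of 12 rose and 2 fell, median 0.17, camera adjusted p = 0.392) did not pass as lists. Nor did heat shock and stress genes (3 of 16 fell and 0 rose, median −0.21, camera adjusted p = 0.109). Cholesterol synthesis genes (1 of 21 fell and 0 rose, median −0.23, camera adjusted p = 0.328) and glycolysis genes (1 of 16 fell and 0 rose, median −0.24, camera adjusted p = 0.0728) did not pass either. At 100 nM 1026 of 14966 genes changed (248 higher, 778 lower) and at 250 nM 2196 (700 higher, 1496 lower). The largest rises at 250 nM were Ceacam10 (128 against 5.86 CPM, 4.45 ± 0.06), Zfp972, Cadm4, Thsd1, S100a9, Frmd6, Hist3h2a and Cd177. The largest falls were Retnla (0.0411 against 147 CPM, −11.74 ± 0.13), Arg1, Penk, Cxcl3, Mmp13, Ppbp, Pf4 and Kcnn3. Between the doses, 606 genes changed from 100 to 250 nM (116 higher, 490 lower), among them Ccnd1 (−2.17 ± 0.06), and the largest falls were Cd200r4, Ccdc80, Stfa3 (32.7 against 281 CPM, −3.10 ± 0.07), Vsig8 and Clec4a2. Counts adjusted over the list alone equalled those given except where shown.

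**Figure D3:**
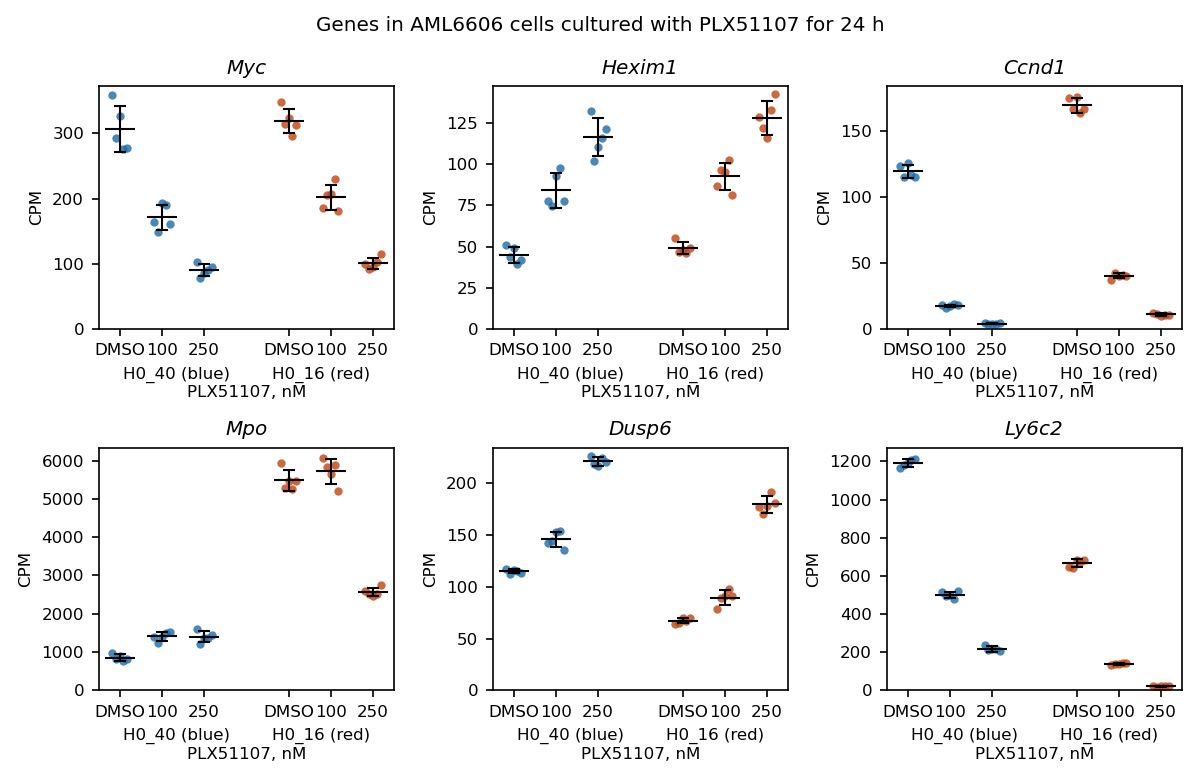
CPM of Myc, Hexim1, Ccnd1, Mpo, Dusp6 and Ly6c2 in the cultured libraries by dose of PLX51107, for cells from H0_40 and H0_16. Each point is 1 library, with the mean ± SD of 5 libraries drawn over them.

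The same question was asked of cells from H0_16, whose marrow had been exposed to both drugs. Myc fell from 319 CPM in DMSO to 202 ± 19.7 at 100 nM (−0.66 ± 0.08, within the fold minimum) and 100.5 ± 8.79 at 250 nM (−1.67 ± 0.09, adjusted p = 8.01e-17). Hexim1 went from 48.9 ± 3.67 to 92.6 ± 8.38 and 128 ± 10.3 CPM (1.39 ± 0.08 at 250 nM). Ccnd1 fell from 169.9 ± 5.53 to 40.2 ± 1.94 and 10.9 ± 0.789 CPM (−2.08 ± 0.04 and −3.96 ± 0.05). Mpo fell at 250 nM (2568 ± 113 against 5486 ± 268 CPM, log2 change −1.09 ± 0.07, adjusted p = 3.98e-15) but was at 0.06 ± 0.07 at 100 nM. Primary granule genes were lower with the preset correlation (8 of 14 fell and 0 rose, median −1.15, camera adjusted p = 0.000298, adjusted p = 0.142 with an estimated correlation), and Prss57, a granule serine protease, fell by −2.79 ± 0.05. Late granule genes were lower likewise (3 of 20 rose and 10 fell, median −1.08, camera adjusted p = 0.000213, adjusted p = 0.166 with an estimated correlation), with Camp at −4.92 ± 0.12 and Chil3 at 37.2 against 677 CPM, −4.18 ± 0.06. Monocyte and macrophage genes fell (1 of 21 rose and 9 fell, median −0.85, camera adjusted p = 0.00523), led by Ly6c2, a surface marker of inflammatory monocytes, from 666 ± 21.6 to 20.8 ± 0.888 CPM (−5.00 ± 0.04, adjusted p = 1.77e-35). At 100 nM 9 of 21 fell and 0 rose (median −0.80, camera adjusted p = 3.4e-08). Ribosome biogenesis and growth genes fell (7 of 50 fell and 0 rose, median −0.82, camera adjusted p = 7.96e-18), with Srm at −1.55 ± 0.06. Ras pathway components were slightly higher (3 of 39 rose and 0 fell, median 0.22, camera adjusted p = 0.00956), with Rasgrp4, an exchange factor of myeloid cells, at 56.3 against 26.6 CPM, 1.08 ± 0.07. Dusp6 rose from 67.2 ± 2.49 to 179.7 ± 7.90 CPM (1.42 ± 0.04, adjusted p = 1.8e-22). Its level was also higher at 250 nM in H0_40 cells (222.8 ± 3.56 against 113.2 ± 2.02 CPM, scaled over all 55 libraries). MAPK output genes as a list did not pass (3 of 22 rose and 4 fell, median 0.06, camera adjusted p = 0.963). BET proteins and P-TEFb regulators were slightly higher (1 of 18 rose and 0 fell, median 0.29, camera adjusted p = 0.00086). Among BET inhibitor response genes 7 of 18 rose and 5 fell (median 0.05, camera adjusted p = 0.993).

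Interferon response genes in H0_16 cells fell at 100 nM (10 of 25 fell and 0 rose, median −0.92, camera adjusted p = 1.24e-06). They were lower at 250 nM (12 of 25 fell and 0 rose, median −0.98, camera adjusted p = 0.00146, adjusted p = 0.076 with an estimated correlation), with Gbp3 at 2.08 against 24.9 CPM, −3.59 ± 0.08. Antigen presentation genes fell at 100 nM (2 of 12 fell and 0 rose, median −0.64, camera adjusted p = 0.0028). At 250 nM they were lower with the preset correlation (6 of 12 fell and 0 rose, median −1.12, camera adjusted p = 0.00704, adjusted p = 0.076 with an estimated correlation). G2 and M phase genes were lower with the preset correlation (0 of 29 changed, median −0.28, camera adjusted p = 0.000208, adjusted p = 0.126 with an estimated correlation). G1 to S phase genes were too (0 of 32 changed, median −0.20, camera adjusted p = 0.00266, adjusted p = 0.126 with an estimated correlation). Of the stress genes, Trib3 (1.14 against 11.9 CPM, −3.37 ± 0.14), Asns (−1.68 ± 0.06) and Chac1 (−1.15 ± 0.10), all induced by amino acid shortage, fell (1 of 16 rose and 3 fell, median −0.21, camera adjusted p = 0.107). The BCL2 family was mixed (2 of 15 rose and 3 fell, median −0.28, camera adjusted p = 0.712), with Bmf at 2.72 ± 0.08 and Bcl2a1a at −1.85 ± 0.05. At 100 nM 989 of 14966 genes changed (190 higher, 799 lower) and at 250 nM 2213 (818 higher, 1395 lower). The largest rises at 250 nM were Zfp972 (71.2 against 6.53 CPM, 3.44 ± 0.11), Rtl5, Trp53inp2, Sesn3, F11r, Thsd1, Snn and Hist1h1c. The largest falls were Retnla and Arg1, which kept 1 and 2 counts in all 5 libraries at 250 nM against 11.6 and 10.1 CPM in DMSO, then Penk (−6.29 ± 0.13), Chdh, Clec12a, Ly6c2, Camp and Myl10. From 100 to 250 nM 635 genes changed (250 higher, 385 lower). The largest rises were Zfp972, Tnfrsf23, Bmf (1.57 ± 0.08), Trp53inp2 and Trp53inp1, and the largest falls Clec12a (3.96 against 70.2 CPM, −4.16 ± 0.06), Camp, Kcnn4, Ly6c2 and Retnlg. Myc fell by −1.01 ± 0.08 between the doses, or −0.98 without library 4 of H0_16 at 100 nM, then short of the fold minimum. Counts adjusted over the list alone equalled those given except where shown.

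The responses of H0_40 and H0_16 cells at 250 nM were close across genes. Their log2 changes had a correlation of 0.807, and of the genes changed in both, 482 rose in both and 1071 fell in both (38.3 and 139.4 by independent draws), while 1 went opposite ways (147). Retnla, Arg1, Penk, Ccnd1, Cd180 and Chil3 fell in both, and Zfp972, Thsd1, Hexim1, Bmf and Trp53inp1 rose in both. The baseline difference between H0_16 and H0_40 cells in DMSO had no single relation to the response of H0_40 cells. Of the genes changed in both, 416 were lower in both (86.8 by independent draws), 39 higher in both (13) and 132 opposite (68.5). With no fold minimum more genes went opposite ways than by independent draws (3510 against 2714), 1282 were higher in both (1432.8) and 1464 lower in both (1280.4). The rank correlation over all genes was 0.025. The Pearson correlation was 0.292, where sharing the DMSO libraries gave 0.489 in simulation, but the covariance was 0.206 against 0.036 in simulation. With those libraries split the correlation was 0.231, the covariance 0.181, and 397.7 genes on average were lower in both.

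**Figure D4:**
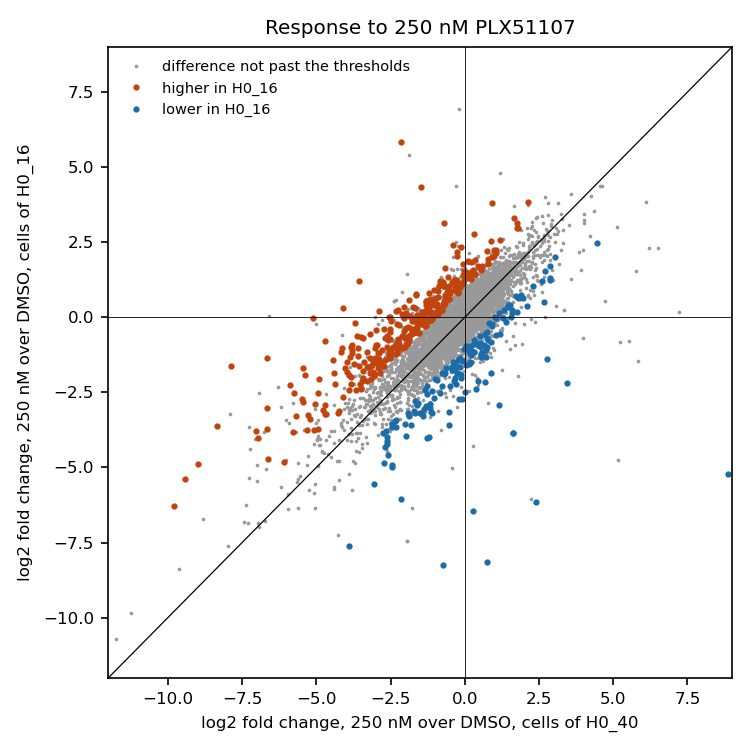
Log2 change at 250 nM PLX51107 in H0_40 cells against that in H0_16 cells, 1 point per gene, with the diagonal. Colour marks the genes whose response differed between the origins, red where H0_16 was the higher and blue where it was the lower.

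Whether the response itself differed between the origins was tested as the log2 change in H0_16 cells minus that in H0_40 cells. Mpo responded in opposite directions at 250 nM, from 856 to 1399 CPM in H0_40 cells and from 5486 to 2568 CPM in H0_16 cells (difference −1.80 ± 0.09, adjusted p = 3.66e-15). Primary granule genes responded lower in H0_16 as a list (median −0.50, camera adjusted p = 2.59e-11), and Mpo, Elane (−1.67 ± 0.15), Gfi1 (−1.77 ± 0.40) and Prss57 (−1.12 ± 0.07) were the 4 of 14 members called. Ly6c2 fell further in H0_16 (difference −2.54 ± 0.05), and so did Clec12a (−2.49 ± 0.07). Late granule genes gave 4 higher and 5 lower differences of 20 (median −0.28, camera adjusted p = 0.125). Monocyte and macrophage genes responded higher in H0_16, that is with smaller falls (4 higher and 1 lower of 21, median 0.71, camera adjusted p = 8.84e-07). Mrc1 led them (2.77 ± 0.13, adjusted p = 3.76e-16), from 152 to 3.32 CPM in H0_40 and from 22.1 to 3.37 CPM in H0_16 cells. Megakaryocyte and platelet genes (5 higher of 8, median 1.19, camera adjusted p = 0.000621) and the mast cell, basophil and eosinophil list (2 higher of 5, median 0.60, camera adjusted p = 0.00624) responded higher as well, with Pf4 at 2.93 ± 0.51 and Gata2 at 2.13 ± 0.21. The monocyte and platelet lists were already lower in H0_16 cells in DMSO, and the same DMSO libraries enter this difference. For them a changed response and a lower start cannot be told apart here. G2 and M phase genes responded lower (median −0.29, camera adjusted p = 3.6e-17, 0 members called), and p53 target genes (median 0.24, camera adjusted p = 0.00302) and cholesterol synthesis genes (median 0.15, camera adjusted p = 0.000837) slightly higher. Primary granule genes and G2 and M phase genes were higher in H0_16 cells in DMSO with the preset correlation. For these 2 lists a changed response and a higher start cannot be told apart either.

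NF-kappa B and inflammatory genes responded higher in H0_16 with the preset correlation (7 of 21, median 0.57, camera adjusted p = 2.55e-06, adjusted p = 0.0977 with an estimated correlation). So did interferon response genes (5 of 25, median 0.42, camera adjusted p = 0.00971, adjusted p = 0.14 with an estimated correlation) and MAPK output genes (1 of 22, median 0.20, camera adjusted p = 0.000465, adjusted p = 0.201 with an estimated correlation). These lists too were lower in H0_16 cells in DMSO with the preset correlation, so the same limit holds. The BET inhibitor response list did not pass for the difference at 250 nM (0 of 18 called, 1 adjusted over the list alone, median 0.08, camera adjusted p = 0.951). Differences were 0.10 ± 0.12, adjusted p = 0.64 for Myc and 0.02 ± 0.12, adjusted p = 0.933 for Hexim1, while Ccnd1 had 0.97 ± 0.07, adjusted p = 1.26e-11, within the fold minimum, Dusp6 0.47 ± 0.06 and Bcl2 −0.80 ± 0.08. In all, 485 of 14966 genes differed in response at 250 nM (322 higher and 163 lower in H0_16) and 117 at 100 nM (55 and 62). The largest higher responses at 250 nM were Mmp13, Penk (3.50 ± 0.39), Nrp1, Pf4, Mrc1, Fads2, Rnase4 and Itih5. Mmp13 was near 0 counts (4.04 ± 1.38, adjusted p = 0.0337) and lost its call without library 1 of H0_16 at 250 nM (adjusted p = 0.401). Among the largest lower responses were Lipg, Clcf1, Ly6c2, Clec12a, Camp, Myl10 and Ceacam10 (−1.98 ± 0.08). Of these, Lipg, Camp and Myl10 were among the largest rises of H0_16 over H0_40 cells in DMSO, and Clcf1 among the largest falls. At 100 nM the largest differences in response were Ankrd37 (1.88 ± 0.15), Pf4, Fads2, F13a1 and Mrc1 upward and Clcf1, Ceacam10 (−1.70 ± 0.08), Atp6v0d2, March1 and Arhgap21 downward. Of the lists, megakaryocyte and platelet genes passed with an estimated correlation too (2 higher of 8, median 0.55, camera adjusted p = 0.00173). The count of 485 came from a test with 5 libraries in each of 4 groups. Counts adjusted over the list alone equalled those given except where shown.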

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

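The splits with group means removed were chosen only after the counts had been seen. The other tests of this part were fixed before.

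The response to PLX51107 differed between H0_16 and H0_40 cells in 117 genes at 100 nM and 485 at 250 nM. Of 100 splits of the same libraries, drawn from 31752, 5 gave as many at 250 nM as the real grouping in a fit of these groups alone (475, highest of the others 1872), which alone would not exclude chance. The other 4 each swapped 1 library per origin, or all but 1, since these 2 cases were counted alike. They called 1578 to 1872 genes, several times the real count. This points to a structure of the samples, the drug effect that such swaps carry. With group means removed first, none of the other splits reached the 475 of the real grouping, and the highest was 1. That 475 came from data with group means kept. The removal takes out the group differences themselves, so this cannot exclude chance for that count. At 100 nM 2 of 100 gave as many (117 in the real grouping, highest of the others 692). With group means removed none of the other splits reached 117 (highest 71), with the same limit as at 250 nM. For each of the other counts the real grouping was the only 1 of 100 splits drawn from 126 to give as many. In fits of the compared groups alone, the real count and the highest of the others were 851 and 1 for H0_20 against H0_40, 345 and 1 for K1_26, 675 and 2 for K1_30, and 294 and 3 for K1_30 against K1_26. In culture they were 1051 and 2 for DMSO cells of H0_16 against H0_40, 884 and 0 at 100 nM and 1973 and 2 at 250 nM in H0_40 cells, and 801 and 13 and 1955 and 2 in H0_16 cells. Between the doses they were 445 and 2 in H0_40 and 476 and 1 in H0_16 cells. Random labels among these libraries are thus an unlikely source of these counts. Splits that mix distinct groups also widen the spread, which lowers their counts. Splits of libraries cannot exclude chance differences between animals or codes.

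Each library was also compared with the other 4 of its group by Dixon's test, in which chance alone picks about 1 in 20 groups. Of 284 tests 28 passed where 14.2 were expected, 7 of 66 on library measures and 21 of 218 on the fixed genes. Library 1 of H0_40 cells at 250 nM had 18100 genes with counts (others 18790 to 19010). The mitochondrial share was 2.27% in library 2 of H0_40 cells at 250 nM (others 2.01 to 2.08), 1.44% in library 4 of H0_16 cells at 100 nM (2.06 to 2.17) and 4.23% in library 3 of H0_40 marrow (3.50 to 3.65). Component scores stood apart in library 5 of H0_16 cells at 100 nM (18.4 on the first, others 21.2 to 22.1), library 5 of H0_16 cells at 250 nM (20.1 on the second, others 13.6 to 14.9) and library 3 of H0_40 marrow (89.9 on the second, others −32.6 to −22.6). In H0_40 marrow, library 4 had Spry2 at 22.5 and Ccnd1 at 143.8 CPM and library 3 had Etv5 at 23.7 CPM. In K1_04, library 2 had Brd2 at 285.8 and library 3 Bcl2 at 60.2 CPM. In K1_26, library 2 had Myc at 271.4 CPM and library 5 Cd180 at 46.5 and Serpini1 at 0. In K1_30, library 1 had Cdk6 at 443.4 CPM and library 5 had Rasgrp1 at 10.3 CPM. Among H0_40 cells, Cd180 was 13.9 CPM in library 4 of DMSO and 1.85 in library 4 of 100 nM, and in library 2 of 250 nM Nras was 149.6 CPM. Among H0_16 cells, DMSO library 5 had Serpini1 at 0.218 and library 1 Spry2 at 10.3 CPM, and library 1 of 250 nM had Bcl2 at 11.3, Cd180 at 1.09 and Cd34 at 5.58 CPM.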

How the results depend on the processing

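Only the alternative without doubted libraries was chosen after results had been seen. Every count of changed genes depends on its fold minimum, and the counts in culture also depend on genes of low expression. With library numbers as a block, a pairing the labels do not state, the counts were 829 for H0_20, 341 for K1_26, 683 for K1_30, 353 between K1_30 and K1_26, 1139 for DMSO cells, 2182 and 2215 at 250 nM in H0_40 and H0_16 cells, and 472 for the difference in response. DESeq2 gave 1000, 472, 850 and 537 for the 4 marrow comparisons and 1152 for DMSO cells. Without the doubted libraries (3 of H0_40, 4 of H0_20, 5 of K1_26 and 5 of K1_30) the marrow counts were 858, 362, 674 and 339. None of the 150 refits without 1 library moved a count by over 1.5 times. Of 335 alternative counts 295 stayed within 1.5 times and 40 did not, and of 34056 alternative values of named genes 32641 kept their call, 421 gained one, 994 lost it and 0 reversed.

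With no fold minimum the counts were 3360 for H0_20 against H0_40, 1358 for K1_26 against K1_04, 2789 for K1_30 against K1_04 and 1806 for K1_30 against K1_26. In culture they were 7898 for DMSO cells of H0_16 against H0_40, 8113 at 100 nM and 10284 at 250 nM in H0_40 cells, 7804 at 100 nM and 10401 at 250 nM in H0_16 cells, 1180 and 3392 for the difference in response at 100 and 250 nM, and 6964 and 7726 between the doses in H0_40 and H0_16 cells. They are larger by construction. The excess of falls seen with the minimum was absent without it in DMSO cells (4180 higher, 3718 lower), in H0_40 cells at 100 nM (4140 and 3973) and 250 nM (5130 and 5154), and in H0_16 cells at 250 nM (5167 and 5234) and between the doses (4011 and 3715). The excess of higher responses at 250 nM was absent too (1674 and 1718), and at 100 nM 325 were higher and 855 lower. At adjusted p under 0.01, K1_30 against K1_26 gave 254.

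The balance of rises and falls for H0_20 against H0_40 turned with library totals only (518 higher, 419 lower) and in limma on log2(TPM + 1) (482 and 299) and log2(TPM + 0.1) (673 and 401). Between K1_30 and K1_26 it turned with DESeq2 (273 and 264), in a fit of only the groups compared (148 and 146) and with all 55 libraries in one fit (780 and 686). For the difference in response at 100 nM it turned in several alternatives, such as library totals (61 and 54) and log2(TPM + 1) (43 and 9), and in many refits without 1 library, so that count has no stable direction.

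With all 55 libraries in one fit, in which marrow and culture share a dispersion, the marrow counts were 2083 for H0_20, 1336 for K1_26, 1860 for K1_30 and 1466 between K1_30 and K1_26. The cultured ones were 703 for DMSO cells, 540 and 517 at 100 nM in H0_40 and H0_16 cells, 30 and 138 for the difference in response at 100 and 250 nM, and 294 and 287 between the doses. Marrow spread more than culture, which is consistent with a shared dispersion raising the first and lowering the second.

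On log2(TPM + 1) limma gave 476 for DMSO cells, 305 and 997 at 100 and 250 nM in H0_40 cells, 261 and 931 in H0_16 cells, 52 and 181 for the difference in response, and 144 and 122 between the doses. On log2(TPM + 0.1) the last 2 were 399 and 416. The stricter filter gave 622 and 648 at 100 nM in H0_40 and H0_16 cells and 401 and 408 between the doses. The larger pseudocount shrinks low genes by construction, and the filter removes them.

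Without genes under 1 mean log2 CPM the correlations were 0.591 for K1_26 with K1_30, 0.232 for H0_20 with K1_30, 0.316 for H0_20 with DMSO cells, 0.893 for the responses at 250 nM, and 0.18 for DMSO cells with the response of H0_40 cells. With controls split they were 0.259 for K1_26 with K1_30 and 0.231 for DMSO cells with that response. Genes changed the same way with no fold minimum numbered 780 for K1_26 with K1_30, 393 for H0_20 with K1_26 (49 with it, and 254 opposite without), 849 for H0_20 with K1_30 (289 opposite), 1838 for H0_20 with DMSO cells, 8597 for the responses at 250 nM and 2746 for DMSO cells with that of H0_40 cells. For H0_20 with K1_30 independent draws would give 331.7 opposite. For H0_20 with DMSO cells 543 went opposite ways, where independent draws would give 954.2. In both pairs the opposite genes lay under that number without the minimum and above it with the minimum. For DMSO cells with the response of H0_40 cells, 3510 went opposite ways where independent draws give 2714, so without the minimum the balance is the reverse. Its rank correlation was 0.025, and −0.111 without genes under 1 mean log2 CPM.

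Of 394 gene list tests, 130 passed camera with the preset correlation, 68 with an estimated correlation, 293 the directional and 346 the mixed form of fry, and 127 with library numbers as a block. The cause of the differences not explained above was not tested.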

Other observations

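The Reactome sets, the chromosome tests on high counts and windows, and the spread slope and level tests were chosen only after results had been seen.

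Reactome sets showed further groups of genes. In DMSO cells of H0_16 against H0_40, genes of chemokine receptors and their ligands were lower (10 of 23 fell, median log2 change −0.81, adjusted p = 2.05e-06, and 0.00292 with an estimated correlation), as were genes of extracellular matrix organization (27 of 118 fell and 8 rose, median −0.28, adjusted p = 1.31e-05, and 0.0318 with an estimated correlation). In K1_30 marrow against K1_04, platelet degranulation genes (53, median −0.34, adjusted p = 2.91e-07, and 0.0142 with an estimated correlation), iron uptake and transport genes (37, median −0.25, adjusted p = 0.000118, and 0.0127) and genes of signalling to RAS (21, median −0.25, adjusted p = 0.000118, and 0.013) were lower, while those of the pre-replicative complex were higher (29, median 0.21, adjusted p = 4.51e-05, and 0.0337). In K1_26 cholesterol biosynthesis was lower (22 genes, median −0.33, adjusted p = 1.1e-05, and 0.0327), and in K1_30 against K1_26 genes of actin dynamics at the phagocytic cup (49, median −0.18, adjusted p = 4.6e-05, and 0.00583).

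Some genes were nearly on or off between groups. Slc47a1, Tex19.1 and Morc1 stood at 28.7, 25.4 and 19.6 CPM in uncultured H0_40 marrow, at 0.14, 0.17 and 0.26 in H0_20, and at 0.12, 0.09 and 0.01 in cultured H0_40 cells in DMSO. Morc1 was also at 6.98 to 21.3 CPM in the AML6613 groups, where the other 2 were at most 0.12. Arhgap21, Pkp4 and Ly75, all on chromosome 2, were 0.55, 0.30 and 0.50 CPM in H0_16 DMSO cells and 73.6, 21.2 and 17.8 in H0_40 DMSO cells. Chromosome 2 genes as a body differed by only −0.016 from the other autosomes between these cells. Rnf217 was 0.18 CPM in K1_30 and 10.2 and 10.7 in K1_04 and K1_26, Dglucy was 197.4 CPM against 33.6 and 37.2, and Mecom was 115 to 173 CPM in AML6613 and at most 1.2 in AML6606.

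Chromosome 12 genes were lower in H0_20 than in H0_40 marrow, by a median log2 of 0.53 against the other autosomes, with 89.7% of 310 genes below 0 (permutation test shuffling genes among chromosomes, p = 1e-04, the smallest that 10000 shuffles can give). Low counts are not likely to be the source, since genes of at least 6 log2 CPM gave −0.537, nor a local run of genes, since 11 of 11 windows of 10 Mb were below −0.2, nor a few libraries, since all 5 H0_20 libraries lay below every H0_40 library. The permutation test treats genes as independent and ignores the spread among libraries, so its p-value does not measure the size of a shift. Small shifts passed it too. For chromosome 7 in K1_26 against K1_04 the difference was −0.054 (permutation test shuffling genes among chromosomes, p = 0.003). In DMSO cells of H0_16 against H0_40 it was 0.041 for chromosome 17 (permutation test shuffling genes among chromosomes, p = 0.04). Against K1_04, the excess on chromosome 12 was 0.547 ± 0.031 in H0_40 marrow and 0.036 ± 0.048 in H0_20 (SD, n = 5), so the shift lies in H0_40. The simplest hypothesis is 1 extra copy of chromosome 12 in the cells of H0_40, but cultured H0_40 cells in DMSO had −0.179 ± 0.033, which argues against copies in all cells of that code. All 6 cultured groups were low on chromosome 12 (−0.251 to −0.157), so an offset of culture or library type stays open. Within culture, DMSO cells of H0_16 lay only 0.034 below those of H0_40, where H0_20 marrow lay 0.53 below H0_40 marrow. Whether H0_16 cells carry extra copies is not known. A subclone lost from culture also stays open. DNA copy number of the H0_40 marrow and of the cells set to culture would test it.

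Chromosome 2 genes were lower in K1_30 than in K1_26 by 0.283 against the other autosomes (the same permutation test, p = 1e-04, with the same limit). Genes of at least 6 log2 CPM gave −0.276, 18 of 18 windows lay below −0.1, and 5 of 5 K1_30 libraries lay below every K1_26 library, so low counts, a local run of genes and a few libraries are unlikely sources. The excess against K1_04 was −0.257 ± 0.008 in K1_30 and 0.018 ± 0.004 in K1_26. A loss of 1 copy in part of the K1_30 cells is a hypothesis that DNA copy number could test, and a copy loss in all cells would be expected to lower expression further.

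Uncultured libraries spread more than cultured ones in weakly expressed genes, with a coefficient of variation of 0.934 and 1.117 against 0.16 below 2 log2 CPM. Cultured libraries thinned to the lowest total gave 0.137. This coefficient leaves out the noise of counting reads, so thinning could hardly raise it and cannot decide on depth. The apparent difference in library type between marrow and culture cannot be told apart from this spread either. Fewer distinct molecules sampled fits, with squared variation falling against CPM at a slope of −0.834 in AML6606 marrow, although it also fell in culture (−0.521, or −0.47 when thinned). Differences between mice stay open, as genes of at least 8 log2 CPM spread 2 times as much in marrow (0.09 against 0.045). Counts of unique molecules, or reads before removal of duplicates, would separate fewer molecules from differences between mice.

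Chromosome 16 genes stood above K1_04 in every AML6606 group, from 0.126 to 0.312. Xist was 82.3 CPM in H0_40 marrow, 18.1 in H0_20 and at most 1.56 in cultured cells, beside Y-linked Ddx3y at 119.9, 111.5 and 55.1 to 60.1 CPM, which could reflect female cells of a host in the marrow. The lower monocyte, platelet and mast cell genes of H0_20 marrow could share that source. Neither was tested.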
